A study of Mus musculus with 10 samples.

How the data were processed

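The series holds bulk RNA sequencing of nonclassical monocytes sorted from mouse bone marrow, with 5 libraries from animals carrying LAIR1 (WT) and 5 from animals lacking it (LAIR1KO). Per the labels' protocols, RNA came from a low-input preparation of sorted cells. Per the submitters' processing notes, reads were aligned with GSNAP to GRCm38.p5. The version of GSNAP, the counting tool, the annotation release, the strand setting and any read filter are not given in the sources used here. The authors deposited one table of raw read counts with 52636 Ensembl genes and 10 columns, and no normalization had been applied to it. Each column was matched to a library by the identifier in the sample title, and 0 columns were left over.

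Gene names, coordinates, exon lengths and GC content were taken from GENCODE M21 on GRCm38, which matched 52489 of the 52636 gene identifiers. The total count per library ran from 12106209 to 15356924. Counts of replicate libraries of a group differed by 15.5 to 78.3 chi-square units per degree of freedom, so no library repeated another within sampling noise. The labels do not say that each library came from a different animal, so p-values measure the spread between these libraries. Because the strand setting is not given, reads from a gene and an overlapping antisense gene could not be told apart. Genes with many near-identical copies had few counts: cytosolic ribosomal protein genes took 0.126% to 0.184% of each library.

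Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), libraries were scaled with TMM, and LAIR1KO was compared with WT by the quasi-likelihood test (glmQLFit, glmQLFTest) with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 13469 genes kept, and an adjusted p under 0.05 was the threshold. Log2 fold changes are LAIR1KO minus WT. Their SE was obtained from the fold change and the F statistic. CPM values use the TMM-scaled library sizes and are given as mean ± SD. All adjusted p-values of single genes are two-sided and come from edgeR unless another tool is named.

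A set of 34 gene lists was fixed before the data were examined. Of these, 30 had at least 4 tested members and were tested with camera in limma 3.58.1 on voom log2 CPM with a preset inter-gene correlation of 0.01, and adjusted over the 30 lists. Camera with an estimated correlation and fry were alternatives. The sex-linked list served as a sample check. Lair1 was also compared between groups with a two-sided exact permutation test of the mean CPM. Intervals on counts are exact Clopper-Pearson intervals at 95% and cover counting error only, since the counts carry no molecular identifiers.

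The genes named in the text followed a rule also fixed before the data were examined. It took Lair1 first. It then took the 10 largest fold changes in each direction among genes past the threshold with a mean log2 CPM of at least 1, for which at least 4 of the 5 LAIR1KO libraries lay on the changed side of every WT library but at most 1. Predicted genes (Gm, Rik, LOC) were replaced by the next gene, which happened 1 time among the higher genes and 0 times among the lower genes. From each list it took up to 4 members past the threshold with the smallest p, or 2 where none passed. It added the most abundant member of each list of another cell type, the sex-linked genes, and genes past the threshold starting within 10 Mb of the start of Lair1. Some genes that the rule takes are not reported here by name, and they remain in the counts.

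The procedure was tested on counts simulated from the means and library sizes of the real genes, with 200 genes changed by known folds among 13204 genes in the fit of LAIR1KO against WT. The changed genes were drawn from those with a mean of at least 2 CPM, so recovery at lower abundance was not measured. The procedure recovered 31.3% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 90.9% of those changed 4-fold. Unchanged genes made up 6.38% of its calls, and 1 of 30 unchanged lists was called. The simulated genes were independent of each other, so this does not measure how camera behaves with correlated genes.

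Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in at least 5 libraries, the replicate number as a block, each library left out in turn, voom with library quality weights, 1 surrogate variable from sva 3.50.0, DESeq2 1.42.0, limma voom, robust dispersion, an adjusted p under 0.1, and a test against a fold of 1.5. Alternatives added after the data were seen were scaling by library totals, removal of each library's trend with GC content and exon length, and leaving out LAIR1KO replicates 4 and 5 together or WT replicates 1 and 4 together.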

Results

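Bulk RNA sequencing was available for nonclassical monocytes, the patrolling subset of blood and marrow monocytes, sorted from the bone marrow of WT and LAIR1KO mice. LAIR1 is an inhibitory receptor of leukocytes that binds collagen domains, and the series asks how it bears on the homeostasis of monocytes and macrophages. There were 5 libraries per genotype. The total count per library was 12106209 to 15356924, and 13469 genes were abundant enough to test.

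Lair1 transcripts were nearly absent from the LAIR1KO libraries. The gene (ENSMUSG00000055541, GRCm38 chromosome 7, 4003402 to 4063204, minus strand) stood at 374 ± 27.7 CPM in WT and 0.226 ± 0.276 CPM in LAIR1KO (SD, n = 5 each; two-sided exact permutation p = 0.00794, the smallest these group sizes can give). The WT libraries held 4230 to 5579 counts each. LAIR1KO replicates 1 to 3 held 3, 10 and 4 counts, and replicates 4 and 5 held 0, which at a limit of 3 counts allows up to 0.234 and 0.217 CPM. In total the LAIR1KO libraries held 17 counts against 24186. Scaled to equal library size this was 0.0629% of the WT level (95% interval 0.0367% to 0.101%). The log2 fold change was -10.58 ± 0.34 (SE; edgeR adjusted p = 1.62e-09), and -11.49 without LAIR1KO replicate 2. Every library matched its genotype label. All 10 libraries expressed Xist, the transcript of the inactive X chromosome, at 92.6 to 159 CPM, and its difference between the groups did not pass (log2 fold change 0.20 ± 0.13, adjusted p = 0.426).

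**Figure D1:**
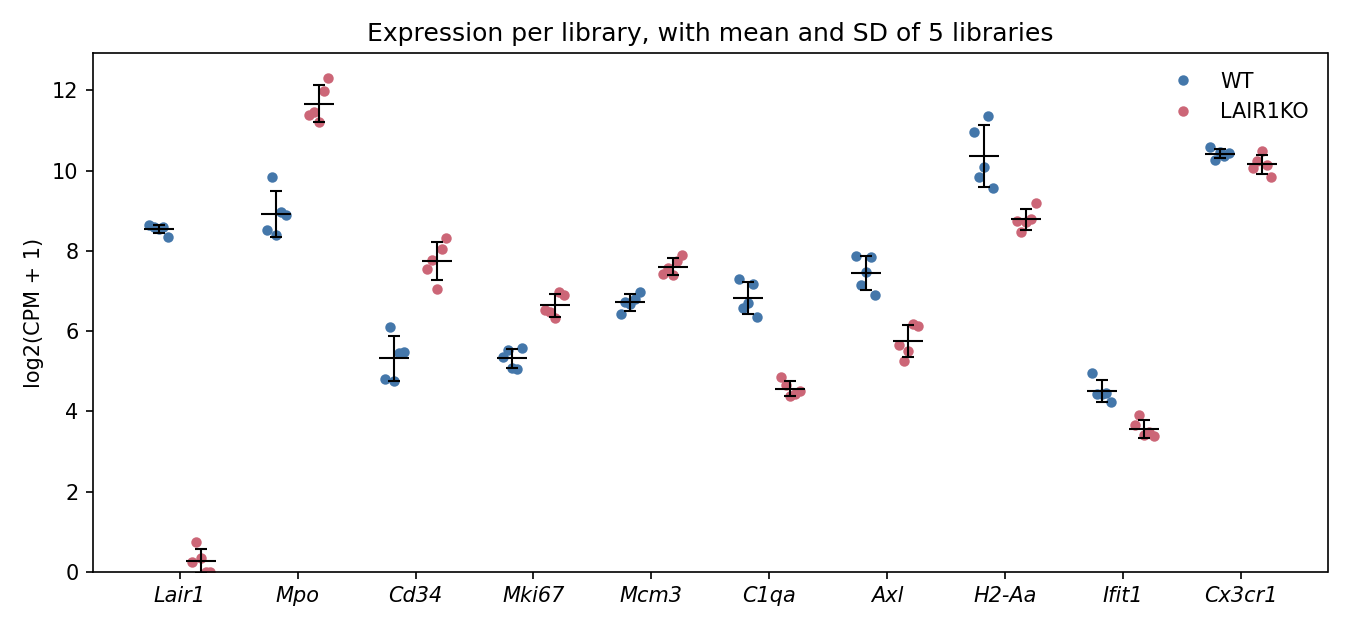
Expression of 10 genes in each library as log2(CPM + 1), WT in blue and LAIR1KO in red, with the mean and SD of 5 libraries. Lair1 fell from 374 to 0.226 CPM, Mpo, Cd34, Mki67 and Mcm3 were higher in LAIR1KO, C1qa, Axl, H2-Aa and Ifit1 were lower, and Cx3cr1 did not pass the test.

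The comparison of LAIR1KO with WT asks which transcripts of nonclassical monocytes differ without LAIR1. In LAIR1KO 10 of 12 myeloid progenitor, 23 of 24 mitosis and 17 of 25 DNA replication genes were higher. Lower were 8 of 13 resident macrophage genes, among them the 3 chains of complement C1q, all 7 MHC class II genes and 10 of 23 type I interferon response genes. Each of these lists passed camera at the preset correlation. With an estimated correlation the resident macrophage list passed and the others did not (adjusted p = 0.0830 to 0.0977). Of 13469 genes, 914 passed the threshold, 688 higher and 226 lower in LAIR1KO. The change exceeded 2-fold for 335 of the higher and 84 of the lower genes. The values of the groups did not overlap for 718 of the 914 genes, and 7.66% of all tested genes showed no overlap, where chance gives 0.794%. Higher genes made up 75.3% of the calls with TMM and 90.1% when libraries were scaled by their totals, a scaling that moved the median of all genes to 0.13. With the GC and length trend removed the share was 65.7%. The first principal component, with 29.1% of the variance, separated the genotypes, and LAIR1KO replicates 4 and 5 lay farthest from WT on it. Leaving out LAIR1KO replicate 4, LAIR1KO replicate 5 or WT replicate 3 alone gave 535, 594 and 585 changed genes. Without LAIR1KO replicates 4 and 5 together 376 genes passed, and without WT replicates 1 and 4 the count was 338. Of the 82 named genes past the threshold, 36 lost their call without the former pair and 38 without the latter. The named progenitor genes other than Flt3, and the named mitosis, C1q and MHC class II genes with Mertk and Axl, passed in both fits.

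Genes of myeloid progenitors, the marrow precursors of granulocytes and monocytes, rose in LAIR1KO. Of 12 tested members 10 were higher and 0 lower (11 higher adjusted over the list alone), with a median log2 fold change of 2.03. Mpo, the myeloperoxidase of granule precursors, rose from 518 ± 233 to 3401 ± 1142 CPM (SD, n = 5; log2 fold change 2.71 ± 0.29, adjusted p = 3.48e-04). The granule proteases Ctsg (2.44) and Prtn3 (1.97) and the stem and progenitor surface marker Cd34 (2.44) rose with it, as did the stem cell factor receptor Kit (2.63, and 1.84 without LAIR1KO replicates 4 and 5). Camera gave the list an adjusted p of 1.11e-14, and an adjusted p = 0.0830 with an estimated correlation. The mean log2 CPM of the list was highest in LAIR1KO replicates 4 and 5, at 6.65 and 6.99, and lay between 4.09 and 5.12 in WT. An antisense gene overlapped the exons of Mpo, with a mean of 534 counts against 27497. The same held for Prtn3, with 948 counts against 1747, and for Cd34, with 17.1 against 1863.

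Mitosis and DNA replication genes were higher in LAIR1KO, and like the progenitor genes they were highest in LAIR1KO replicates 4 and 5. Of 24 mitosis genes 23 passed, all of them higher (24 adjusted over the list alone; median 1.40). The proliferation marker Mki67 rose from 39.5 to 100.4 CPM (log2 fold change 1.35 ± 0.15, adjusted p = 4.61e-04). The ubiquitin-conjugating enzyme Ube2c (1.21), the kinase Aurka (1.08) and the kinesin Kif20a (1.64) also rose. Exons of Ube2c overlapped an antisense gene with a mean of 0 counts, and those of Kif20a one with 1287 counts. Of 25 DNA replication genes 17 were higher and 0 lower (22 higher adjusted over the list alone; median 0.88), among them the ribonucleotide reductase subunits Rrm1 (1.08) and Rrm2 (1.02) and the replicative helicase subunits Mcm3 (0.89) and Mcm5 (0.86). Camera gave adjusted p-values of 3.78e-27 for mitosis and 1.56e-15 for replication, and adjusted p = 0.0834 and 0.0921 with an estimated correlation.

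Resident macrophage genes fell, with the smallest p-values for the 3 chains of C1q, the recognition protein of the classical complement pathway. C1qa went from 115 ± 32.4 to 22.9 ± 3.23 CPM (log2 fold change -2.33 ± 0.18, adjusted p = 6.37e-05), C1qc from 184 to 36.6 CPM and C1qb from 367 to 75.1 CPM. The receptor kinases for apoptotic cells Mertk (-2.43) and Axl (-1.73) were also lower. In all, 8 of 13 tested members fell and 0 rose (11 lower and 1 higher adjusted over the list alone; median -1.39). The most abundant member, Adgre1, which encodes F4/80, stood at 913 and 716 CPM (log2 fold change -0.35 ± 0.12, adjusted p = 0.0947), and it passed without LAIR1KO replicate 3 (adjusted p = 0.0135). Camera called the list with an adjusted p of 6.51e-13, and with adjusted p = 0.00147 when the correlation was estimated.

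All 7 tested MHC class II genes, which present antigen to helper T cells, were lower in LAIR1KO (7 adjusted over the list alone; median -1.57). H2-Aa went from 1487 ± 811 to 447 ± 84.6 CPM (log2 fold change -1.73 ± 0.30, adjusted p = 0.00485), with H2-Ab1 (-1.73), H2-Eb1 (-1.73) and the peptide-loading chaperone chain H2-DMb1 (-1.13) beside it. WT replicates 1 and 4 had the highest H2-Aa values, 2013 and 2648 CPM. Without these 2 libraries the log2 fold change of H2-Aa was -1.05 (adjusted p = 0.0128), that of H2-Ab1 was -1.03, and the median of the list was -1.02. Camera gave an adjusted p of 2.00e-08, and adjusted p = 0.0977 with an estimated correlation.

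Type I interferon response genes fell: 10 of 23 were lower and 0 higher (17 lower adjusted over the list alone; median -0.70). Ifit1 (adjusted p = 0.00491), Usp18 (-1.03) and Isg15 (-1.20), all induced by interferon, and the transcription factor Irf7 (-0.59) passed. Usp18, Isg15 and Irf7 no longer passed without WT replicates 1 and 4 (adjusted p = 0.0891, 0.0924 and 0.0789). Camera gave an adjusted p of 3.93e-13, and adjusted p = 0.0921 with an estimated correlation.

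Some members of the monocyte and macrophage differentiation list and of the inhibitory receptor list were lower. Of 16 monocyte and macrophage differentiation genes 3 fell (5 adjusted over the list alone; median -0.33), among them the transcription factors Maf (-1.75) and Nr1h3 (-0.77). Of 19 inhibitory receptors and phosphatases 4 fell (7 adjusted over the list alone; median -0.31), namely Siglece (-0.99), Clec4a2 (-1.16), the inhibitory Fc receptor Fcgr2b (-0.54) and Cd72 (-0.98). Fcgr2b lost its call without LAIR1KO replicate 4 and without WT replicate 1 or 4 (adjusted p = 0.0573, 0.0533 and 0.0523), and Cd72 without WT replicate 2, 3, 4 or 5 (adjusted p up to 0.0631). Exons of Cd72 overlapped an antisense gene over 41.6% of their length. Camera gave adjusted p = 1.15e-04 for the first list and 7.28e-07 for the second, and adjusted p = 0.0351 for both with an estimated correlation.

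Further lists fell by camera at the preset correlation and lost that call with an estimated one. The estimate was below the preset 0.01 for the integrin and collagen receptor (0.0058), pro-survival (-0.0306) and dendritic cell (-0.0542) lists. Correlated members therefore do not account for the lost calls of these lists. Phagocytosis and lysosome genes had 5 of 20 members lower (12 adjusted over the list alone; adjusted p = 7.24e-11, and 0.0834 with an estimated correlation), including Mertk, Axl, the growth factor precursor Grn (-0.47) and the protease Ctss (-0.51). Grn lost its call in 6 and Ctss in 8 of the 10 fits with 1 library left out. Activating receptors and ITAM signalling had 3 lower and 1 higher of 24 (5 and 1 adjusted over the list alone; adjusted p = 7.95e-06, and 0.161 with an estimated correlation). The activating Fc receptor Fcgr1 fell by 0.99, and its signalling chain Fcer1g by 0.60. Sirpb1a (-0.45) and Lilra6 (0.99) lost their calls in 9 and 8 of those fits, and Fcer1g in 7. Limma voom did not call Lilra6 (adjusted p = 0.0534, and 0.0689 with library quality weights). Immediate early and heat shock genes had 4 of 17 lower (6 adjusted over the list alone; adjusted p = 3.93e-05, and 0.0533 with an estimated correlation): Jun (-0.50), Atf3 (-0.59) and the near-identical copies Hspa1a (-1.08) and Hspa1b (-1.11), whose reads could be split between them. Jun lost its call in 2 of the fits with 1 library left out, Atf3 in 3, Hspa1b in 6 and Hspa1a in 9. Hspa1a also lost it with limma voom (adjusted p = 0.0990, and 0.0781 with library quality weights) and with library totals (0.0698), and Jun with library totals (0.0735). Among integrin and collagen receptors 1 of 14 fell, the mannose receptor Mrc1 (-1.39; 5 lower and 2 higher adjusted over the list alone; adjusted p = 0.00645, and 0.0830 with an estimated correlation). Mrc1, Mertk and Axl are also members of the resident macrophage list, so their falls are counted again here. Among pro-apoptotic genes Bbc3 fell (-0.61, with adjusted p = 0.0673 once the GC and length trend was removed; 1 of 17, and 1 adjusted over the list alone; adjusted p = 0.0193, and 0.161 with an estimated correlation), and the list did not pass without WT replicate 1 (adjusted p = 0.0509), without LAIR1KO replicates 4 and 5 (0.179), with no filter (0.0513) or with library totals (0.0617). The pro-survival list fell as a whole (adjusted p = 0.0310, and 0.0938 with an estimated correlation) while its 1 changed member of 12, Bcl2, rose (0.79; 1 adjusted over the list alone). The pro-survival list did not pass without LAIR1KO replicate 2 (adjusted p = 0.0548), without LAIR1KO replicates 4 and 5 (0.104) or without WT replicates 1 and 4 (0.0570).

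**Figure D2:**
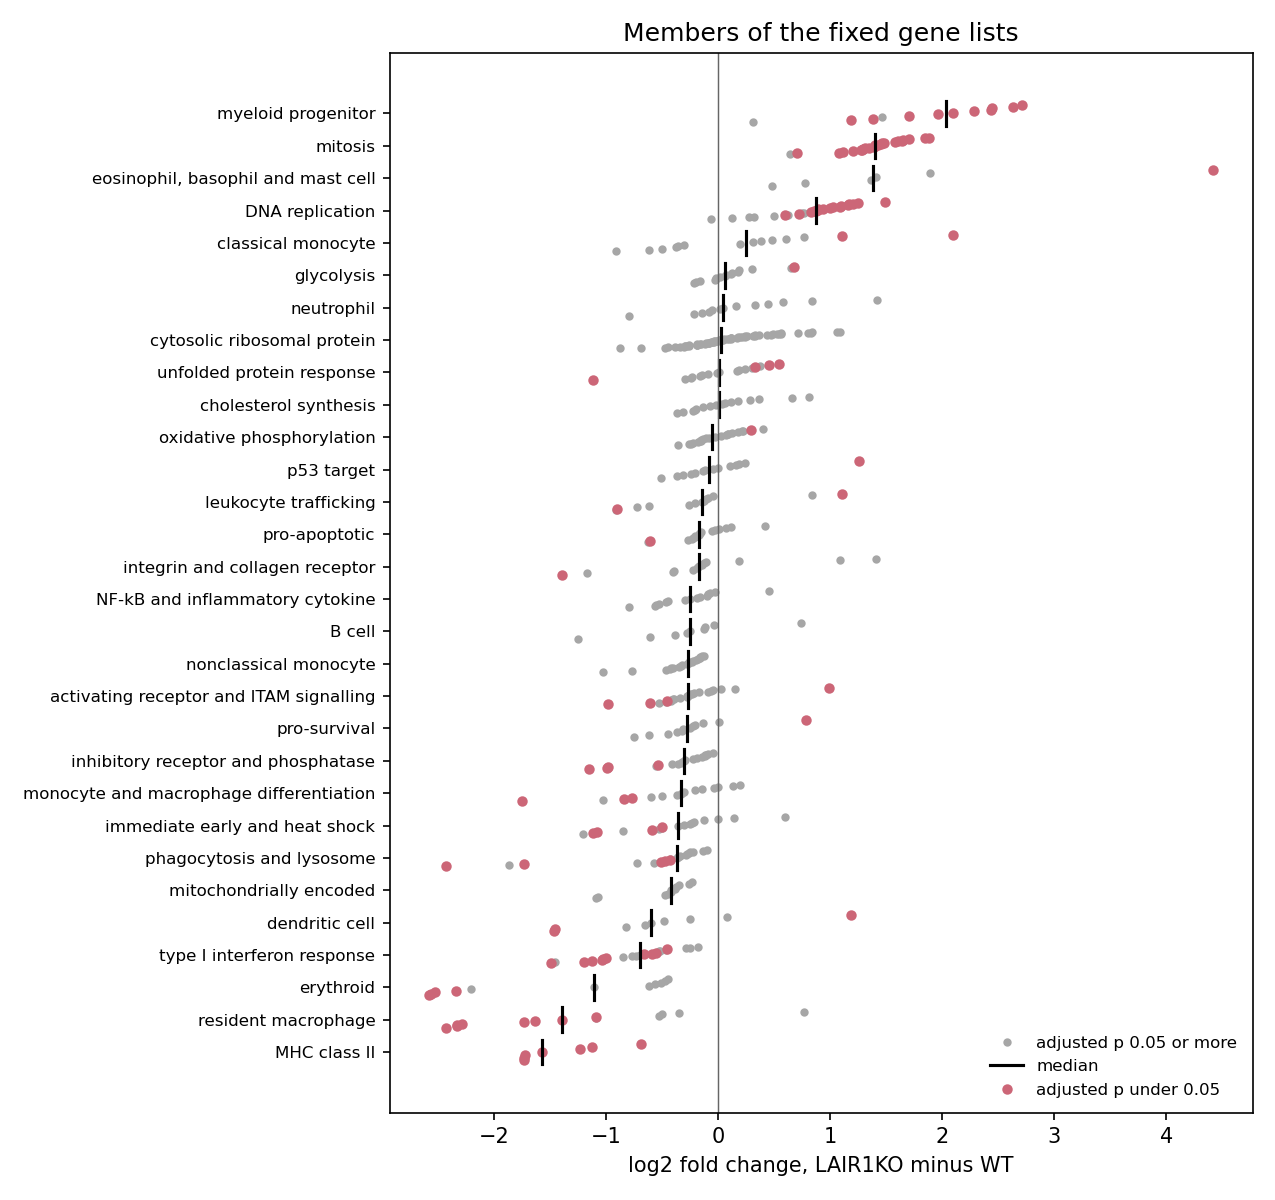
Log2 fold change (LAIR1KO minus WT) of each tested member of the 30 fixed gene lists, with members at an adjusted p under 0.05 in red, other members in grey and the list median as a black bar. Myeloid progenitor, mitosis and DNA replication lists had medians of 2.03, 1.40 and 0.88, and MHC class II and resident macrophage lists -1.57 and -1.39.

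The identity genes of nonclassical monocytes remained abundant. None of the 20 members passed singly (0 adjusted over the list alone; edgeR, adjusted p from 0.0778 for Itgax), yet all 20 fold changes were below 0, with a median of -0.27. Camera gave the list an adjusted p of 1.57e-06, and adjusted p = 0.161 with an estimated correlation. Itgax, an integrin chain, had a log2 fold change of -0.40 ± 0.13 and the transcription factor Klf2 one of -0.77 ± 0.25. Itgax passed without WT replicate 5 (adjusted p = 0.0468) and Klf2 without WT replicate 1 (adjusted p = 0.0445). Among classical monocyte genes 2 of 14 rose (3 higher and 4 lower adjusted over the list alone), among them F13a1, the coagulation factor XIII chain, from 84.6 to 362 CPM (2.10). The list as a whole did not pass (adjusted p = 0.505).

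Markers of other cell types moved in both directions. The 4 haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were lower by 2.34 to 2.58 on the log2 scale (4 of 11 erythroid genes, 5 adjusted over the list alone; adjusted p = 0.00392, and 0.323 with an estimated correlation). Hbb-bs was highest in WT replicate 2, at 711 CPM. Without that library the log2 fold changes were -1.29 for Hba-a1, -1.55 for Hba-a2, -1.39 for Hbb-bs and -1.32 for Hbb-bt, and none of the 4 passed (adjusted p = 0.0567 to 0.105). Limma voom called none of these 4 genes (adjusted p = 0.113 to 0.132), nor did it with library quality weights (0.111 to 0.137). Hba-a2 lost its call in 5 and each of the other haemoglobin genes in 7 of the 10 fits with 1 library left out. The pairs of haemoglobin genes are near-identical, so reads could be split between them. Among 6 eosinophil, basophil and mast cell genes Prg2, a granule protein of eosinophils, rose (4.42; 2 higher adjusted over the list alone; adjusted p = 0.00146, and 0.0834 with an estimated correlation), with values from 2.79 to 85.3 CPM in LAIR1KO, and it no longer passed without WT replicates 1 and 4. Without LAIR1KO replicate 4 its log2 fold change was 3.39. Limma voom gave Prg2 a log2 fold change of 3.60 and did not call it without or with library quality weights (adjusted p = 0.153 and 0.114). Prss34, the most abundant member, was at 13.6 and 18.9 CPM (adjusted p = 0.824). It stood at 50.4 CPM in WT replicate 1, at 0 to 12.0 in the other WT libraries and at 11.2 to 34.2 in LAIR1KO. Of 9 dendritic cell genes Clec9a (-1.46) and Siglech (-1.46) fell and Flt3 (1.18), shared with the progenitor list, rose (2 lower and 1 higher adjusted over the list alone; adjusted p = 0.0266, and 0.0938 with an estimated correlation). The dendritic cell list did not pass without LAIR1KO replicate 3 (adjusted p = 0.0779), without LAIR1KO replicates 4 and 5 (0.0587), with no filter (0.0589) or with the GC and length trend removed (0.0553). Siglech lost its call in 6 of the 10 fits with 1 library left out and with limma voom (adjusted p = 0.0613, and 0.0596 with library quality weights). Tcf4, the most abundant, was at 113 and 94.7 CPM (adjusted p = 0.191). Neutrophil genes (adjusted p = 0.197; 0 of 13, and 0 adjusted over the list alone) and B cell genes (adjusted p = 0.147; 0 of 9, and 0 adjusted over the list alone) did not pass. The neutrophil list passed as higher without WT replicate 1 (adjusted p = 0.0232), without WT replicates 1 and 4 (0.00234) and without LAIR1KO replicates 4 and 5 (0.0238), and the B cell list as lower without WT replicate 5 (adjusted p = 0.0264). Their most abundant members were Csf3r at 414 and 399 CPM and Ighm at 1138 and 1106 CPM. Ly6g (1.42 ± 0.54), Padi4 (0.58 ± 0.23), Vpreb3 (-1.25 ± 0.47) and Cd79a (-0.39 ± 0.30) had the smallest p-values there.

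Too few members were measured to test 3 lists of other cell types. Nkg7, of T and NK cells, rose (1.35; 1 of 2 tested, and 1 adjusted over the list alone) and lost its call in 3 of the fits with 1 library left out. Pf4, a platelet chemokine, fell by 2.22 on the log2 scale (1 of 3, and 3 adjusted over the list alone), and Ppbp, at 71.3 CPM in WT replicate 5, did not pass (adjusted p = 0.103). Among stromal and endothelial genes 0 of 3 passed (2 adjusted over the list alone), with Cxcl12 at 14.5 and 6.24 CPM (adjusted p = 0.108, and 0.0356 without WT replicate 4) and Sparc at -2.22 ± 0.77 (adjusted p = 0.110).

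Most metabolic and stress lists did not pass as groups. The lists for leukocyte trafficking, unfolded protein response, glycolysis, ribosomal proteins, p53 targets, oxidative phosphorylation and cholesterol synthesis had camera adjusted p-values of 0.0679, 0.401, 0.401, 0.444, 0.784, 0.938 and 0.945. Single members passed in 5 of them. Of 13 leukocyte trafficking genes 1 rose and 1 fell (1 higher and 2 lower adjusted over the list alone), and the list passed as lower without WT replicate 2 or LAIR1KO replicate 3 (adjusted p = 0.0323 and 0.0424) and with library totals (0.0489). The ribosomal protein list passed as higher without WT replicates 1 and 4 together (adjusted p = 0.0223). Its genes took only 0.126% to 0.184% of each library, so either outcome says little about ribosomal protein transcripts. The chaperones Calr (0.45), Pdia4 (0.54) and Pdia6 (0.33) rose and Trib3 (-1.11) fell (4 higher and 1 lower adjusted over the list alone). Hexokinase Hk3 (0.68), the mitotic protein Gtse1 (1.26) and the ATP synthase subunit Atp5b (0.30) rose, 1 of each list also when adjusted over the list alone. Pdia4, Pdia6, Trib3 and Atp5b lost their calls in 6, 8, 7 and 8 of the fits with 1 library left out. No cholesterol gene passed, with Sqle at 0.66 ± 0.26 (adjusted p = 0.0339 without LAIR1KO replicate 3) and Srebf2 at -0.23 ± 0.11, and no ribosomal protein gene did, with Rpl29 at 1.06 ± 0.35 and Rpl27 at 0.80 ± 0.27 (0 adjusted over the list alone for both lists). NF-kB and inflammatory cytokine genes fell by camera (adjusted p = 0.00645, and 0.130 with an estimated correlation) with 0 of 15 members past the threshold and 3 lower adjusted over the list alone. Relb had a log2 fold change of -0.53 ± 0.15 and Nfkb2 one of -0.29 ± 0.09. Without LAIR1KO replicate 1 both passed (adjusted p = 0.0130 and 0.0399), as did Relb without WT replicate 1 (adjusted p = 0.0393), and the list did not pass without LAIR1KO replicates 4 and 5 together (adjusted p = 0.112). Mitochondrially encoded transcripts fell by camera (adjusted p = 0.00733, and 0.484 with an estimated correlation) with 0 of 11 members past the threshold (0 adjusted over the list alone). The mitochondrial list did not pass without WT replicate 1 or LAIR1KO replicate 4 (adjusted p = 0.0765 and 0.0570), without WT replicates 1 and 4 (0.116) or without LAIR1KO replicates 4 and 5 (0.373). Their 2 smallest p-values belonged to mt-Atp6 (-1.09 ± 0.45) and mt-Rnr2 (-1.07 ± 0.46).

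Of the 30 lists, 20 passed camera at the preset correlation, 4 higher and 16 lower in LAIR1KO, and 3 passed with an estimated correlation: resident macrophage, inhibitory receptor and phosphatase, and monocyte and macrophage differentiation. The medians of the inhibitory receptor and differentiation lists, -0.31 and -0.33, lay near the -0.27 of the nonclassical monocyte list. Whether these lists fell more than monocyte genes in general was not tested. In lists where edgeR called 0 members, the number at an unadjusted p under 0.05 was 8 for nonclassical monocytes, 11 for ribosomal proteins, 3 for NF-kB and inflammatory cytokines, 2 each for neutrophils, stromal and endothelial cells and mitochondrially encoded transcripts, and 1 each for B cells and cholesterol synthesis. DESeq2 called 2 nonclassical monocyte, 2 stromal and endothelial, 3 NF-kB and 1 ribosomal protein genes and 0 in the others, and limma voom called 0 in each of them. Divisions of the same 10 libraries other than by genotype gave up to 23 lists where 4 of 5 libraries of each genotype stayed together, and up to 18 where 3 did.

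The largest single changes held further genes outside the lists. Higher in LAIR1KO were Lhfpl2 (3.86), Tspoap1 (3.19), Bpifc (3.09), the kinesin Kif17 (3.03), the potassium channel subunit Kcng1 (2.87), Zfp507 (2.83) and the mucin Muc13 (2.83). Tspoap1 had an SE of 0.39 and an adjusted p of 6.81e-04. Lower were the interferon-induced GTPase Gbp2b (-2.34) and the integrin chain Itga9 (-2.34). Zfp507 and Itga9 each lost their calls in 3 of the 10 fits with 1 library left out, and Gbp2b in 8. Limma voom did not call Zfp507 and Gbp2b (adjusted p = 0.0830 and 0.109), and with library quality weights it called neither these nor Itga9 (0.0665, 0.0927 and 0.0560). Without LAIR1KO replicates 4 and 5 Lhfpl2, Zfp507 and Gbp2b stood at 3.08, 1.49 and -3.14 and did not pass (adjusted p = 0.0829, 0.215 and 0.0632). Lhfpl2 and Bpifc lay at 0.428 and 0.628 CPM in WT, near the lower limit of measurement.

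Within 10 Mb of Lair1 on chromosome 7, 6 of 86 other tested genes passed, or 6.98% (95% interval 2.60% to 14.6%), against 6.78% of genes elsewhere (one-sided Fisher's exact p = 0.532). They were Prpf31 (0.41), Lilra6 (0.99), Ttyh1 (1.57), Epn1 (-0.53), Cox6b2 (1.17) and the DNA ligase Lig1 (0.83). Of these, Lig1 starts at 13277283 and the others between 3629985 (Prpf31) and 5080235 (Epn1), around Lair1 at 4003402 to 4063204. A smaller window was not tested. All of the 6 but Ttyh1 lost their calls in 3 to 8 of the 10 fits with 1 library left out.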

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

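The tests of progenitor cells, dilution, macrophages and dendritic cells below were chosen after the results were seen, and the GC and length correction was added after the data were seen, while the divisions of the libraries were planned before.

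One library stood far from the other 4 of its genotype for 4 genes in 5 of 210 groups of values (105 named genes in each genotype), where chance alone gives about 5% of groups. The gap to the nearest library, as a share of the whole range on the log2 scale, was 0.815 for Kit in WT, where replicate 2 had 23.7 CPM against 7.19 to 8.99 in the others. It was 0.752 for Mertk in LAIR1KO, with replicate 5 at 0.507 CPM against 0.959 to 1.17. It was 0.752 for Cd72 in WT (replicate 1 at 14.6 CPM against 27.0 to 33.1) and 0.743 for Cd72 in LAIR1KO (replicate 1 at 8.12 CPM against 13.6 to 16.2). For Xist in LAIR1KO it was 0.794, with replicate 2 at 159 CPM against 100.3 to 110 CPM.

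A random division of these 10 libraries is argued against for the number of changed genes, but not for the number of changed lists. Divisions that mix the genotypes also mix any difference between animals, sorts or batches that ran along with genotype, so they cannot exclude one. Of 100 divisions of the 10 libraries into 5 and 5, 1, the real one, gave as many as 914 genes, and the highest other gave 2. For the lists, 5 of 100 divisions gave 20 or more, with 23 in the highest other. The other 4 of these kept 4 of 5 libraries of each genotype together, as did 17 divisions in all, and so carried part of the genotype difference. The 82 divisions that kept 3 together gave at most 18 lists, with a median of 6.

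The higher progenitor, mitosis and DNA replication genes were weighed first. A GC content or gene length trend is argued against, since removing it left the median of the members at 0.945 of its value (1.18 against 1.25) and all 3 lists past the threshold. More myeloid progenitors among the sorted cells remain a candidate explanation for the cell cycle genes. Across the 10 libraries the cell cycle score rose with the progenitor score within genotypes (slope 0.60, 95% interval 0.36 to 0.84), and at equal progenitor score the genotypes differed by -0.055 (95% interval -0.55 to 0.44), against 1.07 (log2) without adjustment. The progenitor scores of the genotypes did not overlap (at most 5.12 in WT, at least 5.77 in LAIR1KO), so the adjustment reaches beyond the measured values. Whether the sort for nonclassical monocytes removed progenitors could not be checked here. An effect of LAIR1 on the monocytes themselves, or on the number of progenitors that pass the gate, was not tested.

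The lower C1q, macrophage and MHC class II genes were weighed second. Dilution of the monocytes by progenitors is argued against as the whole cause, as far as these genes are expressed by the monocytes. The median of the pattern differed by -1.21 from that of the nonclassical monocyte list (95% interval -1.48 to -0.77). That interval came from 10000 resamplings of genes, so it treats genes as independent and leaves out the spread between libraries. MHC class II genes moved together (estimated correlation 0.92), so it may be too narrow. The pattern was picked after its low medians were seen, so only the size of the difference, not its sign, bears on dilution. The comparison was not repeated without WT replicates 1 and 4. Fewer resident macrophages cannot be told apart from lower expression: 12 of the 13 members of the list lay below 0, and their log2 fold changes had an SD of 0.97 against a median SE of 0.22, but monocytes express some of them, such as Adgre1 at 913 CPM in WT, and these would fall less if macrophages were lost. Fewer dendritic cells cannot be told apart either: their markers, leaving out Flt3, had a median 0.95 above that of the MHC class II genes (SD 0.54), but 0.31 above it (SD 0.56) without WT replicates 1 and 4, and Clec9a and Siglech fell by 1.46. Whether the sort for nonclassical monocytes removed macrophages and dendritic cells could not be checked here. A lower expression in LAIR1KO monocytes stays open as a hypothesis.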

How the results depend on the processing

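No named gene or list reversed its direction where it was called. All 914 changed genes that could be fitted kept their sign in every alternative. These fits share most or all of the libraries in which the genes were called, so a kept sign is not independent support. Of the 82 named genes past the threshold, 52 kept their call in all 10 fits that left out 1 library. Counts of changed genes (all, higher, lower) ran from 535 to 1170, 422 to 789 and 113 to 381 in those fits, with the fewest calls without LAIR1KO replicate 4 and the most without LAIR1KO replicate 3. The number of lists ran from 19 to 21, and over the 10 fits 5 list calls ended and 4 were gained. Counts stayed within 1.5 times under RLE and upper-quartile scaling, both filters, voom with and without quality weights and robust dispersion. They also did with the GC and length trend removed, added after the data were seen (925 genes, 608 higher and 317 lower).

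Other counts moved further, and the cause was not tested unless named. A surrogate variable gave 1431 genes, 565 of them lower, and DESeq2 gave 1523, 513 lower, with 528 adjusted p-values missing. An adjusted p under 0.1 gave 1474, 445 lower, by its looser threshold. The test against a fold of 1.5 gave 142, 117 higher and 25 lower, by its stricter null. Camera with an estimated correlation called 3 lists, and fry 19 (25 in either direction). Directional fry ended the calls of the erythroid and mitochondrially encoded lists (adjusted p = 0.168 and 0.255). It gained leukocyte trafficking as lower (adjusted p = 0.0161) and kept the other list calls. Among the alternatives added after the data were seen, library totals gave 1379 genes, 1243 higher and 136 lower. Leaving out LAIR1KO replicates 4 and 5 gave 376, 236 and 140, and leaving out WT replicates 1 and 4 gave 338, 266 and 72, with fewer libraries in each fit. The sex covariate was not run, because the libraries did not split by sex.

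The replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated from -0.08 to 0.05, and 0 WT and 0 LAIR1KO libraries correlated best with their own number. The replicate block gave 600 genes, 478 higher and 122 lower, and 20 lists. Simulated 1.5-fold changes were recovered in 31.3% of cases, so smaller changes could be missed at this depth and number of libraries. Genes of low abundance were not among those simulated as changed.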

Other observations

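The tests in this part were chosen after the results were seen. So were the genes named in this paragraph and the next, which lie outside the fixed lists. They were picked singly from the changed genes and stand for no tested group. Ms4a7, a membrane protein of monocytes and macrophages, had a log2 fold change of -2.21, the complement C3a receptor C3ar1 -2.09, Aif1, which encodes IBA1, -1.85, the chemokine Cxcl16 -1.97 and Wfdc17 -1.53. The endotoxin co-receptor Cd14 fell by 0.67, and the lysosomal protease Lgmn by 0.69. The interferon-induced genes Ifi27l2a (-1.17), Bst2 (-0.61) and Ifitm3 (-0.61) fell as well. Each of these had an edgeR adjusted p under 0.05, and all but Ifitm3 kept it in the 10 fits with 1 library left out. Ifitm3 lost it without WT replicate 1, 2 or 4 and without LAIR1KO replicate 2, 4 or 5 (adjusted p up to 0.0736).

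Among single genes that rose, the transcription factor Myc had a log2 fold change of 2.06, the cell cycle kinases Cdk4 and Cdk6 0.97 and 1.31, the ribosome biogenesis factors Nop58, Dkc1 and Gnl3 0.73, 1.03 and 1.37, and the one-carbon enzymes Shmt1, Shmt2 and Mthfd1 1.80, 1.32 and 1.35, each with an edgeR adjusted p under 0.05. The calls of these genes held in the 10 fits with 1 library left out. The fixed list of ribosomal proteins did not pass camera (adjusted p = 0.444). Its genes took only 0.126% to 0.184% of each library, so this says little about ribosomal protein transcripts.

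Tspoap1 and Mpo, both among the 10 largest rises under the naming rule, are neighbours on GRCm38 chromosome 11. Tspoap1 lies at 87760541 to 87785928 and Mpo at 87793581 to 87804413. Gm11505, the predicted gene replaced under the naming rule, overlaps Mpo on the opposite strand and had a log2 fold change of 2.74. Because the strand setting is not given, its counts could not be separated from those of Mpo.

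A chromosome segment carried along with the knockout allele could place changed genes near Lair1. The share of changed genes was 6.98% within 10 Mb and 6.78% elsewhere (one-sided Fisher's exact p = 0.532). The former's interval, 2.60% to 14.6%, leaves room for an excess, so the segment cannot be told apart from no segment with 86 genes. The changed genes there, other than Lig1, started between 3629985 and 5080235, close to Lair1. The test over the whole window does not address a shorter segment.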
